A study of Mus musculus with 6 samples.

How the data were processed

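Cells were sorted from the dentate gyrus of naive mice with Kdm4a shRNA or control shRNA. Per the labels' protocols, the tissue was microdissected and dissociated with papain, 2000 EYFP-positive cells per tube were sorted, and cDNA was made with the SMART-Seq HT kit and sequenced on an Illumina HiSeq instrument. That kit yields full-length cDNA and does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name the builds GRCm38 and mm10 and the tool edgeR, without a role for any of them. The aligner, the counting method and the annotation are not given in the sources used here.

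The authors deposited 1 table of 34745 rows with a gene symbol, 6 columns of FPKM (fragments scaled by gene length and library depth), and their own comparison. Per the file headers, the comparison columns are a log2 fold change and a p-value. The deposited log2 fold equals the log2 ratio of the mean FPKM of the groups, with no pseudocount. The deposited p-value is unadjusted, and its test is not given in the sources used here. In 2253 rows the fold cell holds a spreadsheet error where the Kdm4a shRNA libraries are at 0, and 27 rows hold a number in place of a symbol. There were 34678 distinct symbols, and 126 rows shared a symbol with another row. Of the rows, 9997 were at 0 in every library. Gapdh, a gene with many processed pseudogenes, was listed at only 0.317 to 1.12 FPKM per library, against 52.5 to 198 FPKM for Actb, so values of genes with near-identical copies are uncertain.

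Groups and replicate numbers were taken from the labels. Coordinates, exon lengths and overlaps came from the GENCODE M21 annotation of GRCm38, to which 32630 rows matched by symbol. Over rows with fewer than 15 rebuilt fragments, 99.8% had values in whole-number ratios across libraries (tolerance 0.03), and 54.2% of 8539 such rows came out whole in every library with the M21 exon length (tolerance 0.05 fragments). The size of 1 fragment at those lengths gave the depth of each library, 6425440 to 7663030 fragments. A gene at 0 in a library of this depth can still be present below a floor of 3 fragments. The fragments behind Kdm4a were taken as the smallest whole numbers in the ratio of its values, and the interval of their ratio as an exact binomial one. A second interval took the group sums of its fragments at the M21 exon length, rounded, and was chosen after seeing the data. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was at least 44.5 for every pair. The 50 most abundant genes held 32.0% to 37.9% of all FPKM in a library.

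The test fixed beforehand for counts does not apply to FPKM, so the one fixed for normalized values was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), two-sided, for genes at 1 FPKM or more in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale. Samples were not paired in the fit. There were 33 gene lists, of which 29 had at least 4 tested members. They were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 29 lists, and again with an estimated correlation and with fry. The lists, the tests, the rule for named genes and most alternatives below were fixed before the data were examined.

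The rule named Kdm4a, Trpm7 and Ythdc2, then the 12 largest changes per direction among genes past the threshold. As none passed, it named the 6 genes per direction with the smallest unadjusted p whose groups did not overlap, with a mean of at least 1 FPKM in the higher group and a symbol that is not a Gm number, clone name, bare identifier or pseudogene. From each list it named the 2 members with the highest mean, of which a part is given, and a gene it names is not reported here. The test was run on simulated data with the spread of the 10933 real genes. Genes changed 2-fold, 4-fold or 16-fold were drawn only from the more highly expressed ones, so their rates do not cover low genes. The noise was normal and independent, so shifts that many genes of a library share were absent. The test recovered 0% of 67 genes changed 2-fold, 37.3% of 67 changed 4-fold and 90.9% of 66 changed 16-fold, with 1 false call among 87. The 87 also hold 1 of 30 further genes changed 2-fold together as a simulated list. Alternatives were quantile normalization, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, the replicate number as a block, leaving out each library, limma-voom on rebuilt fragments, and removal of per-library trends with GC content and exon length. The last 2 were chosen after seeing the data. Depth, matching and intervals were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and bedtools 2.31.1.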

Results

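The data were RNA-seq profiles of cells sorted for the yellow fluorescent protein EYFP from the dentate gyrus of naive mice. The dentate gyrus is the part of the hippocampus whose main neurons are the granule cells. Neurons carried either an shRNA against Kdm4a or a control shRNA, an shRNA being a short hairpin RNA that lowers a chosen transcript. Kdm4a encodes a JmjC-type histone demethylase that removes methyl groups from H3K9 and H3K36. There were 3 libraries with control shRNA and 3 with Kdm4a shRNA, each from 2000 sorted cells. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Values were FPKM per gene as deposited. Depth estimated from the steps between low values was 6792628, 7306686 and 7663030 fragments in control libraries 1, 2 and 3, and 7313572, 6425440 and 6550863 fragments in Kdm4a shRNA libraries 1, 2 and 3. Of the 34745 listed genes, 16803, 17859 and 18609 had a value above 0 in control libraries 1, 2 and 3 and 16767, 15882 and 16428 in Kdm4a shRNA libraries 1, 2 and 3, so each Kdm4a shRNA library had fewer than each control library. At 1 FPKM or more the counts overlapped, with 9671, 10921 and 11657 genes in control and 10459, 9723 and 9934 genes in Kdm4a shRNA libraries. The comparison of the groups addressed which transcripts differ when Kdm4a is knocked down in dentate gyrus neurons, in a study of how Kdm4a acts on the allocation of memories to neurons.

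The targeted transcript was low in all libraries and lower in those with Kdm4a shRNA. Kdm4a (ENSMUSG00000033326.15, GRCm38 chromosome 4, 118136957 to 118180043, minus strand) stood at 0.112, 0.269 and 0.256 FPKM in control libraries 1, 2 and 3. It was listed at 0 in Kdm4a shRNA libraries 1 and 2 and at 0.0333 FPKM in library 3. The smallest whole fragment numbers that give these values were 43 over the control group and 2 over the Kdm4a shRNA group. From these numbers the depth-scaled ratio was 4.99% of control, with a 95% exact interval of 0.585% to 19.2%. A count of 0 allows up to 0.0447 FPKM in Kdm4a shRNA library 1 and up to 0.0509 FPKM in library 2, and the interval and these limits cover counting error only. They depend on the fragment numbers: with the exon length of the GENCODE M21 annotation the values come to 27 and 1 fragments, rounded and not whole in each library. The ratio was then 3.97% (0.0970% to 24.1%), and the limits were 0.0709 and 0.0807 FPKM. No library of one group reached into the range of the other, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. Kdm4a lay below the expression filter of the test across genes. With no filter its log2 fold change on the log2(FPKM + 1) scale was −0.26 (SE 0.0581, limma-trend adjusted p = 0.80). That scale understates changes of low genes. In the authors' deposited table, Kdm4a had an unadjusted p of 0.0612.

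Trpm7 and Ythdc2 were examined as genes known to be of interest to the study. Trpm7, a cation channel fused to a kinase that passes magnesium, calcium and zinc, averaged 2.84 ± 0.695 FPKM (SD, n = 3) in control and 6.66 ± 1.49 FPKM (SD, n = 3) in Kdm4a shRNA libraries, a ratio of 2.34. Its gene lies on GRCm38 chromosome 2, 126791565 to 126876230, minus strand. All 3 Kdm4a shRNA values, from 5.57 to 8.35 FPKM, lay above the 3 control values, from 2.27 to 3.62 FPKM. The log2 fold change was 0.99 (SE 0.43, limma-trend unadjusted p = 0.0453, adjusted p = 0.49), so the difference did not pass correction over all genes. The two-sided exact permutation test gave p = 0.1, its smallest possible value. Of the 10933 genes tested, 761 lay wholly higher in Kdm4a shRNA libraries in the same way, and Trpm7 ranked 1006 by limma-trend p. In the authors' deposited table, Trpm7 had an unadjusted p of 0.014. Ythdc2, an RNA helicase that reads the m6A mark, averaged 1.26 ± 0.293 FPKM in control and 1.12 ± 0.596 FPKM in Kdm4a shRNA libraries (SD, n = 3 each). Its values overlapped between groups, with a log2 fold change of −0.13 (limma-trend adjusted p = 0.94). Ythdc2 lies on GRCm38 chromosome 18, 44827746 to 44889724, plus strand.

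**Figure D1:**
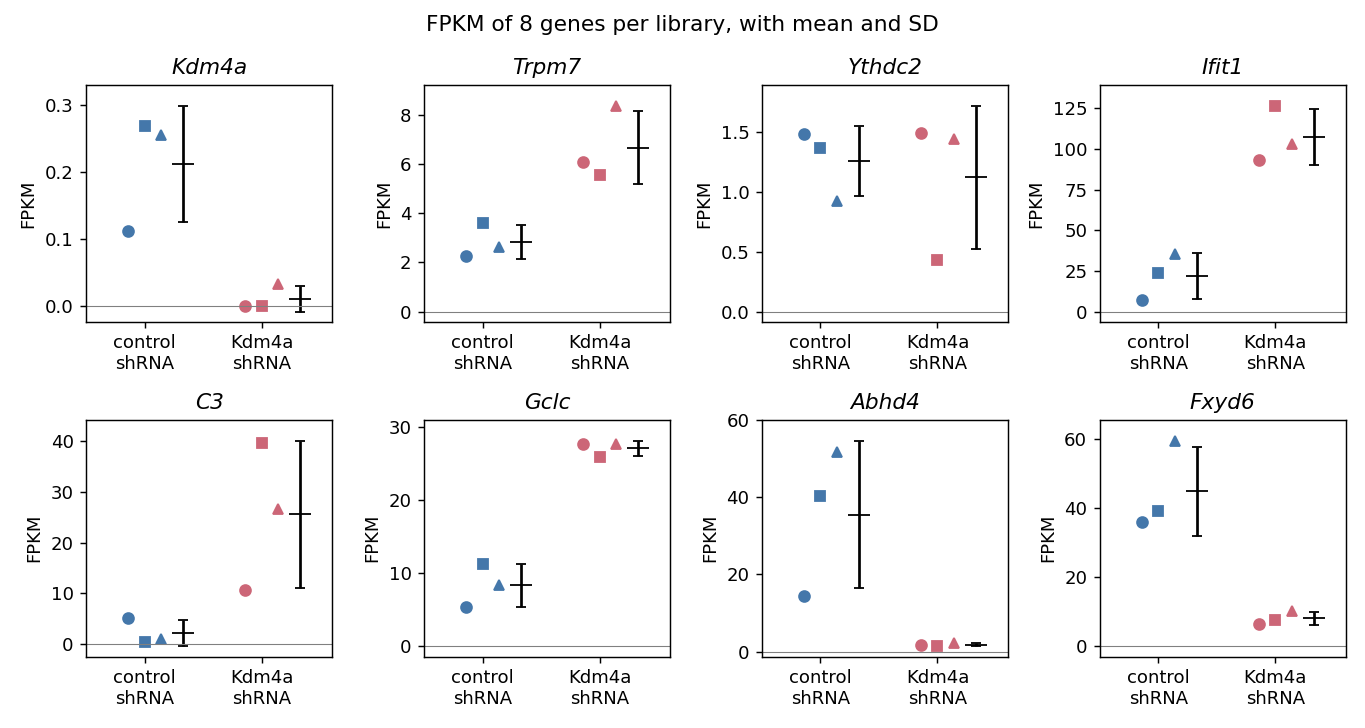
FPKM of Kdm4a, Trpm7, Ythdc2, Ifit1, C3, Gclc, Abhd4 and Fxyd6 in each library (linear axes), control shRNA in blue and Kdm4a shRNA in red, with circles, squares and triangles for libraries 1, 2 and 3. The horizontal mark and bar beside each group are the mean and SD of its 3 libraries, and the groups overlap for Ythdc2 but not for the other 7 genes.

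Lists of glial markers had high medians in every library and lists of neuronal markers low ones. The median over 17 microglia and macrophage markers lay between 210 and 398 FPKM per library. It was 57.9 to 179 FPKM for astrocyte markers and 46.1 to 103 FPKM for oligodendrocyte markers. Granule cell markers had a median of 0.435 to 2.42 FPKM and interneuron markers of 0.0240 to 0.252 FPKM. Ctss, a lysosomal protease abundant in microglia, averaged 4121 ± 1217 FPKM in control and 5877 ± 2604 FPKM in Kdm4a shRNA libraries, while Prox1, the transcription factor of granule cells, ranged from 2.78 to 5.47 FPKM over the 6 libraries. Oligodendrocyte precursor markers had medians of 4.604 to 13.4 FPKM, and endothelial and mural markers of 0.612 to 4.62 FPKM. Control library 1 also stood apart from the other control libraries. Pearson's r of log2 values across genes, which are not independent replicates, was 0.95 between control libraries 2 and 3 and from 0.79 to 0.88 over all other pairs. On the first principal component, which held 36.5% of the variance, control library 1 lay at −35.2, within the range of the Kdm4a shRNA libraries at −4.90, −52.5 and −26.4, and control libraries 2 and 3 lay at 45.1 and 73.9. On the second, with 24.2% of the variance, control library 1 lay at −72.98, away from the other 5 libraries, which lay from −5.78 to 42.8.

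**Figure D2:**
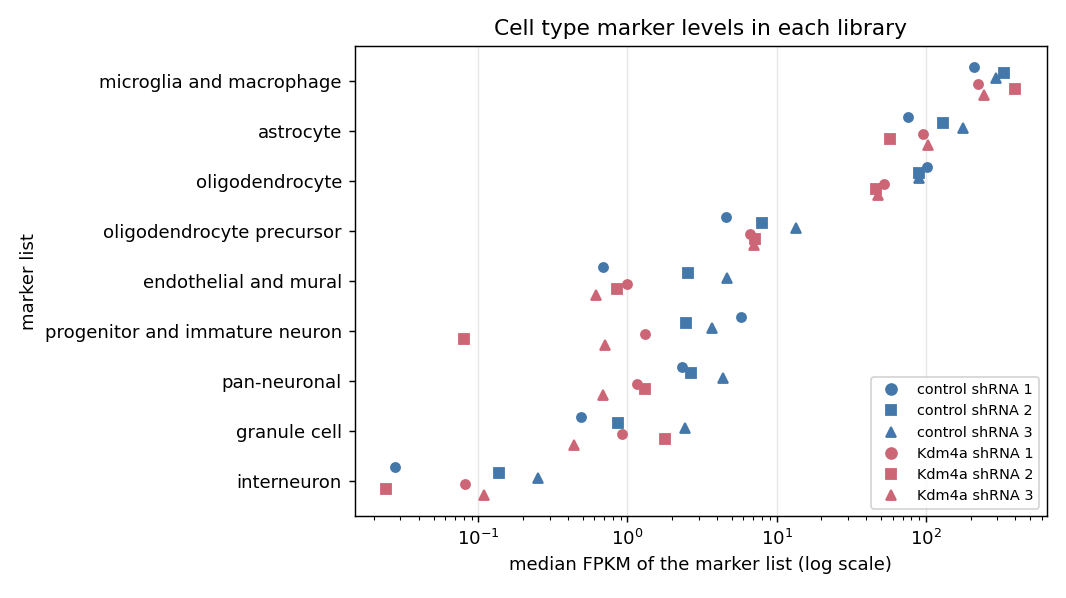
Median FPKM of the genes of each marker list (horizontal log axis) in each library, control shRNA in blue and Kdm4a shRNA in red, with circles, squares and triangles for libraries 1, 2 and 3. Microglial medians, from 210 to 398 FPKM, lie above pan-neuronal medians, from 0.688 to 4.38 FPKM, in all 6 libraries, and the pan-neuronal list was written after the data were seen.

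No single gene passed the test between the groups. Among 10933 genes at 1 FPKM or more in at least 3 libraries, limma-trend found 0 higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p being 0.26. At an unadjusted p under 0.05 there were 371 higher and 713 lower genes, against 547 expected by chance in all. After quantile normalization, which moved the median of all genes by 0.12 on the log2 scale, these counts were 541 and 616, so the excess of lower genes depended on the scaling. limma-voom on rebuilt fragments also gave 0 and 0 at adjusted p under 0.05, and 356 higher and 575 lower unadjusted. The 3 values of one group lay wholly above those of the other for 761 genes higher and 912 lower in Kdm4a shRNA libraries, 15.3% of the genes tested, where chance gives 10%. Both chance figures are averages, and a single split can stray far from them where genes of a library shift together. At an unadjusted p under 0.05, other splits of the 6 libraries gave from 179 to 1480 genes, against 1084 for the real split. Without control library 1, 6 genes were higher and 23 lower at an adjusted p under 0.05, and among the lower were Tubb4a, Tuba1a, Junb, Jund, Tlr2 and Abhd4, named after their values were seen. The library left out lay within or near the Kdm4a shRNA range for some of them, with Jund at 6.703 FPKM against 3.29 to 11.98 FPKM, Junb at 46.7 against 62.3 to 114.8 FPKM and Tlr2 at 71.4 against 30.6 to 65.8 FPKM. Tubb4a stood at 91.01 FPKM in that library, against 42.1 to 60.3 FPKM, Tuba1a at 51.2 against 30.1 to 36.3 FPKM and Abhd4 at 14.4 against 1.53 to 2.33 FPKM. The unadjusted counts were 738 higher and 1298 lower without that library, 179 and 407 without control library 2, and 265 and 354 without control library 3.

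The higher genes with the smallest p, none of which passed correction, were Spata33, C3, Nme5, Ifit1, Pnp2 and Gclc. C3, the central component of complement (GRCm38 chromosome 17, 57203970 to 57228136), averaged 2.14 ± 2.57 FPKM in control and 25.6 ± 14.5 FPKM in Kdm4a shRNA libraries (SD, n = 3), with a log2 fold change of 3.21 (SE 0.67, limma-trend adjusted p = 0.28). Ifit1, an interferon-induced protein that binds viral RNA (GRCm38 chromosome 19, 34640871 to 34650009), averaged 22.1 ± 14.2 and 107 ± 17.1 FPKM, and its 3 Kdm4a shRNA values, from 93.1 to 126 FPKM, lay above the highest control value of 35.3 FPKM. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, averaged 8.33 ± 2.99 and 27.1 ± 1.02 FPKM. Spata33 averaged 0.6002 ± 0.531 and 12.7 ± 7.81 FPKM, and Nme5 4.39 ± 2.84 and 23.01 ± 6.57 FPKM. Pnp2, a purine nucleoside phosphorylase, averaged 0.940 ± 0.822 and 11.2 ± 5.61 FPKM, and its reads are uncertain because it overlaps Gm49342 and has the near-identical copy Pnp.

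The lower genes with the smallest p, again without passing correction, were Wdr55, Spc24, Abhd4, Fxyd6, Cenph and Ttc9b. Abhd4, a lipase in the synthesis of N-acyl ethanolamines (GRCm38 chromosome 14, 54254188 to 54270637), averaged 35.5 ± 19.1 FPKM in control and 1.83 ± 0.440 FPKM in Kdm4a shRNA libraries (SD, n = 3), with a log2 fold change of −3.52 (SE 0.52, limma-trend adjusted p = 0.26). Fxyd6, a regulator of the sodium pump, averaged 44.8 ± 12.8 and 8.07 ± 1.96 FPKM. Spc24 and Cenph, which are parts of the kinetochore, stood at 10.04, 5.68 and 6.97 FPKM and at 11.4, 6.85 and 3.71 FPKM in control libraries 1, 2 and 3, and both were listed at 0 in all 3 Kdm4a shRNA libraries. Wdr55 averaged 9.38 ± 1.32 and 0.186 ± 0.240 FPKM and overlaps Dnd1, and Ttc9b averaged 5.77 ± 1.13 and 0.133 ± 0.231 FPKM and overlaps Map3k10, so both values are uncertain. Without control library 1, the adjusted p of Abhd4 was 0.0426 and that of Wdr55 and of Spc24 was 0.0459.

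Interferon response genes were higher in Kdm4a shRNA libraries as a list. Of 33 tested members, 29 had a positive and 4 a negative log2 fold change, with a median of 0.80 (limma camera, preset correlation, adjusted p = 3.93e-05 over 29 lists). With an estimated correlation the adjusted p = 0.84, so the call was lost. Ifitm3, a membrane protein that blocks virus entry, averaged 266 ± 192 FPKM in control and 553 ± 274 FPKM in Kdm4a shRNA libraries, and Ifi27 averaged 110 ± 13.03 and 196 ± 53.9 FPKM (SD, n = 3 each). No member passed over all genes, and 1 member, Ifit1, passed when adjusted over the list alone (limma-trend adjusted p = 0.034). The list median was 1.41, 11.6 and 14.8 FPKM in control libraries 1, 2 and 3 and 6.16, 19.2 and 15.1 FPKM in Kdm4a shRNA libraries 1, 2 and 3. Without control library 1 the median was 0.28 (camera adjusted p = 0.24), and without Kdm4a shRNA library 2 it was 0.30 (0.070). Microglial markers, the most abundant marker list here, had 7 positive and 9 negative members (median −0.14, camera adjusted p = 0.95).

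Markers of progenitors and immature neurons were lower in Kdm4a shRNA libraries. Of 9 tested members, 8 had a negative log2 fold change, with a median of −1.08 (limma camera, preset correlation, adjusted p = 0.00304), and the adjusted p = 0.63 with an estimated correlation. Hes5, a Notch target of neural stem cells and astrocytes, averaged 51.8 ± 34.0 FPKM in control and 3.63 ± 5.35 FPKM in Kdm4a shRNA libraries, and Sox11, a transcription factor of immature neurons, averaged 35.4 ± 45.4 and 12.5 ± 6.78 FPKM (SD, n = 3 each). None passed over all genes, and 2 passed as lower when adjusted over the list alone, Hes5 and Neurod1, the latter named after its values were seen at 17.4 ± 8.74 and 2.81 ± 3.42 FPKM. Without control library 1 the camera adjusted p of the list was 0.13, with the median at −1.07. The smaller number of genes above 0 in the Kdm4a shRNA libraries goes in the same direction as this list. Oligodendrocyte markers, which did not pass as a list, had a median log2 fold change of −0.42 (camera adjusted p = 0.059), and 4 of 12 members passed as lower adjusted over the list alone, named after their values were seen. They were the myelin genes Mag, Cnp, Mobp and Ugt8a, of which Cnp averaged 106 ± 29.4 and 45.2 ± 9.55 FPKM. The list depended on the setting. Its median was −0.06 without control library 1 (camera adjusted p = 0.79) and 0.01 after removal of GC and length trends (0.11), against −0.51 without control library 2 (0.0397), −0.69 without control library 3 (9.2e-05) and −0.41 after quantile normalization (0.0137). With an estimated correlation the adjusted p = 0.84. Mal, at 596 ± 444 and 443 ± 127 FPKM, overlapped between groups.

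Zinc finger (Zfp) genes were lower as a list. Of 196 tested members, 139 had a negative and 57 a positive log2 fold change, with a median of −0.41 (limma camera, preset correlation, adjusted p = 0.00304), and the adjusted p = 0.74 with an estimated correlation. Many Zfp genes encode DNA-binding repressors that recruit H3K9 methylation, but the most abundant member, Zfp36, encodes an RNA-binding protein that promotes mRNA decay. Zfp36 averaged 282 ± 228 and 73.1 ± 24.7 FPKM, and Zfp706 93.4 ± 36.7 and 126 ± 68.8 FPKM (SD, n = 3 each). No member passed over all genes or adjusted over the list alone. After quantile normalization the list median was −0.23, with the median of all genes at 0.04. The list median was −0.73 with a pseudocount of 0.1 and −0.76 with limma-voom on rebuilt fragments. This direction, too, is that of the smaller number of genes above 0 in the Kdm4a shRNA libraries. Nuclear-encoded respiratory chain genes were higher as a list, with 56 of 77 members positive and a median of 0.23 (limma camera, preset correlation, adjusted p = 0.0071), and the adjusted p = 0.84 with an estimated correlation. Cox6b1 averaged 622 ± 58.0 and 642 ± 99.3 FPKM and Ndufc2 493 ± 69.1 and 591 ± 166 FPKM. This call was lost after quantile normalization (median 0.14, adjusted p = 0.27) and without control library 3 (median 0.14, adjusted p = 0.15), Kdm4a shRNA library 2 (adjusted p = 0.085) or Kdm4a shRNA library 3 (median 0.15, adjusted p = 0.14).

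**Figure D3:**
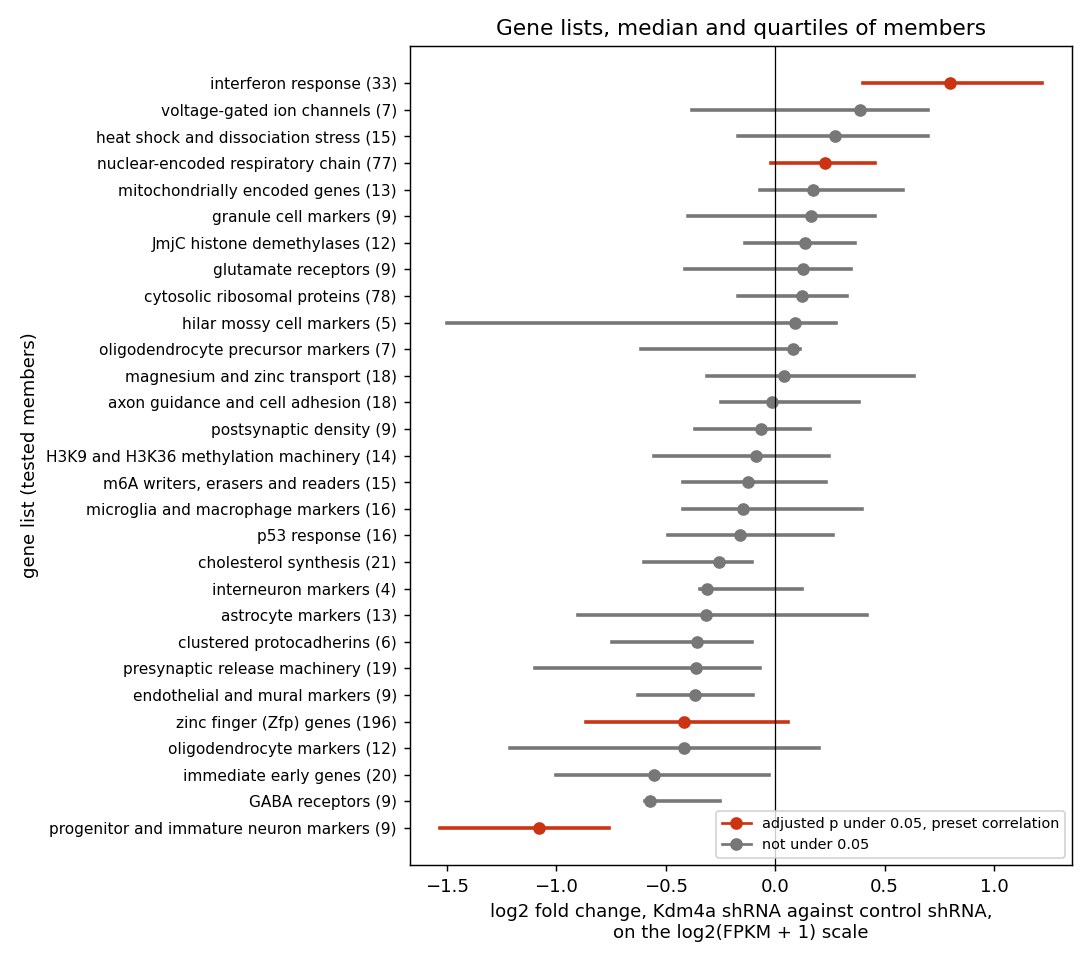
Log2 fold change of the tested members of each of 29 gene lists (horizontal axis, log2(FPKM + 1) scale), as median (point) and quartiles (bar), with the number of tested members in parentheses. The 4 lists in red had a camera adjusted p under 0.05 with a preset correlation, from 0.80 for interferon response to −1.08 for progenitor and immature neuron markers, and none of the 29 passed with an estimated correlation.

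The other 25 lists did not pass the camera test. Immediate early genes, which neuronal activity and tissue dissociation induce, had 5 positive and 15 negative members (adjusted p = 0.17), with Junb at 552 ± 553 FPKM in control and 91.1 ± 26.7 FPKM in Kdm4a shRNA libraries and Fos at 321 ± 154 and 189 ± 14.0 FPKM. Without control library 1 that list had a median of −0.98, against −0.55 with all libraries, and an adjusted p of 0.0102. The median was −0.33 without control library 2 (adjusted p = 0.22) and −0.27 without control library 3 (adjusted p = 0.50). GABA receptors had 1 positive and 8 negative members (adjusted p = 0.17) and presynaptic release machinery 4 and 15 (adjusted p = 0.17), with Snap25, a vesicle fusion protein, at 39.5 ± 18 and 15.1 ± 7.27 FPKM. With a mean of at least 5 FPKM required, the presynaptic list had a median of −1.45, against −0.36, and an adjusted p of 0.0397. At the main filter its median was −0.62 without control library 1 (adjusted p = 0.092), −0.21 without control library 3 (adjusted p = 0.50) and −0.56 without Kdm4a shRNA library 2 (adjusted p = 0.12). The GABA receptor median of −0.57 became −0.82 without control library 1 (adjusted p = 0.067) and −0.15 without control library 3 (adjusted p = 0.50). The adjusted p was 0.52 for voltage-gated ion channels, 0.95 for glutamate receptors, 0.95 for the postsynaptic density, 0.65 for axon guidance and cell adhesion, and 0.65 for clustered protocadherins. Among lists related to the knocked down enzyme it was 0.65 for JmjC histone demethylases, with Jmjd1c at 5.93 ± 2.25 and 9.41 ± 2.06 FPKM, 0.99 for the H3K9 and H3K36 methylation machinery, with Cbx3, which binds methylated H3K9, at 15.8 ± 1.64 and 7.87 ± 3.68 FPKM, and 0.95 for m6A writers, erasers and readers. It was 0.30 for magnesium and zinc transport, with the metallothionein Mt1 at 2054 ± 702 and 1529 ± 404 FPKM, 0.31 for heat shock and dissociation stress, 0.94 for the p53 response, 0.21 for cytosolic ribosomal proteins, 0.21 for mitochondrially encoded genes and 0.36 for cholesterol synthesis. Some of these calls depended on single libraries. Cytosolic ribosomal proteins had a median of 0.20 without control library 1 (adjusted p = 0.0165), against 0.12 with all libraries and −0.01 without Kdm4a shRNA library 2 (adjusted p = 0.89). Mitochondrially encoded genes had a median of 0.49 without Kdm4a shRNA library 1 (adjusted p = 0.00116), against 0.17 with all libraries and −0.12 without control library 3 (adjusted p = 0.90).

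Among the other marker lists the camera adjusted p was 0.94 for granule cells, 0.90 for hilar mossy cells, 0.95 for interneurons, 0.94 for astrocytes, 0.94 for oligodendrocyte precursors and 0.21 for endothelial and mural cells. Calb2, a calcium-binding protein of mossy cells and interneurons, passed as lower adjusted over the mossy cell list alone (34.8 ± 20.4 and 5.13 ± 4.65 FPKM), and was named after its values were seen. So did Neurod6, a transcription factor of pyramidal neurons, over the list of CA1 and CA3 pyramidal cells (12.4 ± 8.80 and 1.53 ± 2.59 FPKM). Only 2 members of that list were tested, and the values of Neurod6 overlapped between the groups (limma-trend adjusted p over all genes 0.43). Apart from the genes given, no member of any list fixed beforehand passed when adjusted over its list alone. The lists of Trpm channels, of CA1 and CA3 pyramidal cells, of choroid plexus and ependymal cells and of erythrocytes had too few members above the filter for a list test. Tmem212, an ependymal gene, averaged 10.4 ± 17.9 and 10.2 ± 17.7 FPKM, and the globin gene Hbb-bs 0.299 ± 0.297 and 0.375 ± 0.120 FPKM.

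The authors' deposited table gave an unadjusted p under 0.05 to 337 genes higher and 942 lower in Kdm4a shRNA, out of 22164 with a p-value. Benjamini-Hochberg adjustment of those p-values left 13 genes under 0.05, of which 1 was higher and 12 were lower. The higher one was Mir155hg, the host transcript of the microRNA miR-155, at 84.1, 69.5 and 0.746 FPKM in Kdm4a shRNA libraries 1, 2 and 3 and at no more than 0.514 FPKM in any control library. Among the lower ones were Abhd4, Cenph, Tubb4a and Neurod4, a proneural transcription factor at 2.51, 7.86 and 6.21 FPKM in control libraries 1, 2 and 3 and listed at 0 in all 3 Kdm4a shRNA libraries. Mir155hg, Tubb4a and Neurod4 were named after their values were seen. Of the genes at an unadjusted p under 0.05 in the limma-trend fit, 556 also had one in the authors' deposited table. For all 556 the fold in the fit had the same direction as the ratio of the mean FPKM of the groups. The deposited fold is that same ratio, and the fit used the same FPKM values, so this agreement was nearly fixed in advance.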

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

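The limma-voom fit on rebuilt fragments and the removal of GC and length trends were chosen after seeing the data. Settings chosen beforehand for counts (DESeq2 size factors, the DESeq2 test, limma-voom on counts and the edgeR likelihood ratio test) were not run, since the values are FPKM, and the stricter filter, quantile normalization, limma-voom and GC alternatives gave no value for Kdm4a. With a pseudocount of 0.1 the log2 change of Kdm4a was −1.46 in place of −0.26, since the pseudocount of 1 exceeds every value of this gene. Counts of genes at an adjusted p under 0.05 were 0 higher and 0 lower under every alternative except 2. With no filter they were 11 and 6, and 9 lists passed. These 17 genes were at most at 0.366 FPKM in any library. Each was at 0 in every library of 1 group and varied little in the other, so the calls rest on a very small spread within groups. Gm10463, for example, stood at 0 in all control libraries and at 0.0474, 0.0539 and 0.0529 FPKM in Kdm4a shRNA libraries 1, 2 and 3. Leaving out 1 library gave 0 to 6 higher and 0 to 23 lower genes and 2 to 5 lists, and the genes came only without control library 1, whose removal leaves 2 control libraries that resemble each other. With an estimated correlation 0 lists passed, and with fry 0. The remaining alternatives left 4 to 6 lists. With the replicate number as a block there were again 0 and 0 genes and 4 lists, and 355 and 726 genes at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at −0.03, 0.04 and 0.04, and not every library correlated best with its own number, so the numbers are not taken as pairs.

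Over 80 genes and 11 lists under these alternatives, 1117 of 1191 values kept their direction and side of the threshold, 15 lost a call, 19 gained one, 0 reversed and 40 changed sign without passing in either fit. None of the 80 genes passed in the main fit, so none had a call to lose. All 15 lost calls fell on the 4 lists that passed there. The 1117 values are thus no measure of how stable those 4 calls were. The interferon list had adjusted p between 4.05e-12 and 0.24 over the fits with a preset correlation, the highest without control library 1. The progenitor list had a median of −2.38 with a pseudocount of 0.1 and −2.86 with limma-voom, against −1.08. Of genes at an unadjusted p under 0.05, 65.8% were lower, from 57.2% to 70.0% without each library in turn, 53.2% after quantile normalization and 52.4% after removal of GC and length trends. The cause of these changes was not tested. At 6425440 to 7663030 fragments and 3 libraries per group, the simulated test recovered 0% of 67 single 2-fold changes and 1 of 30 genes changed 2-fold together, so changes of that size were rarely detected one gene at a time.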

Other observations

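The pan-neuronal, mitotic and microglial activation lists and their tests, the comparison of the interferon list with microglial markers and the test of marker levels for other cells were chosen after the results were seen. Genes of mitosis and DNA replication were lower in Kdm4a shRNA libraries, in a list that leaves out the cell cycle genes first noticed. Of 31 tested members, 29 had a negative log2 fold change, with a median of −1.01 (limma camera adjusted p = 1.43e-06 over 3 lists, and adjusted p = 0.0427 with an estimated correlation). These p-values are no independent support, since lower cell cycle genes in these same libraries prompted the list. Adjustment over 3 lists is also milder than over 29 lists. With an estimated correlation, the camera p of the progenitor list was 0.0217 unadjusted and 0.63 adjusted over 29 lists. The mitotic median was −1.77 with limma-voom on rebuilt fragments and −1.58 with a pseudocount of 0.1. Rrm2, a subunit of ribonucleotide reductase, averaged 13.9 ± 5.71 FPKM in control and 2.15 ± 1.67 FPKM in Kdm4a shRNA libraries, the spindle motor Kif11 3.04 ± 0.810 and 0.312 ± 0.541 FPKM, and Tpx2, a spindle assembly factor, 2.37 ± 0.198 and 0.250 ± 0.246 FPKM (SD, n = 3 each). Pcna, at 52.2 ± 31.9 and 51.3 ± 20.4 FPKM, overlapped between groups. No member passed over all genes or adjusted over the list alone.

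Pan-neuronal markers were also lower, with a median log2 fold change of −1.12 over 14 tested members (camera adjusted p = 0.000264), and the adjusted p = 0.090 with an estimated correlation. Tubb3, a neuronal tubulin, averaged 6.49 ± 2.10 and 0.482 ± 0.390 FPKM, and the RNA-binding protein gene Elavl3 5.27 ± 1.98 and 0.483 ± 0.611 FPKM. These genes and Stmn3, at 44.4 ± 19.5 and 15.9 ± 5.01 FPKM, were the 3 of 14 members that passed as lower adjusted over the list alone, and 0 passed over all genes. Map2, at 3.91 ± 0.497 and 3.80 ± 1.003 FPKM, and Gap43, at 38.1 ± 30.8 and 47.7 ± 15.04 FPKM, overlapped between groups. The list median was 2.31, 2.68 and 4.38 FPKM in control libraries 1, 2 and 3 and 1.15, 1.31 and 0.688 FPKM in Kdm4a shRNA libraries 1, 2 and 3. Of the pan-neuronal genes, Snap25, Syn1 and Syt1 are also in the presynaptic list. Granule cell markers were not lower as a list, with 5 positive and 4 negative members and a median log2 fold change of 0.16. Only 9 of its 17 members were tested. Most of the untested ones had a lower mean in Kdm4a shRNA libraries, such as C1ql2 at 3.78 ± 3.85 and 0 FPKM, but Pdzd2 had a higher one. Among the tested members, Prox1 stood at 3.89 to 5.47 FPKM in Kdm4a shRNA and 2.78 to 3.10 FPKM in control libraries (limma-trend adjusted p = 0.72). Stxbp6, the member with the highest mean, was lower without overlap, at 8.98 ± 3.01 FPKM in control and 3.51 ± 1.12 FPKM in Kdm4a shRNA libraries (limma-trend adjusted p = 0.47). The list thus does not show whether granule cell transcripts were spared. The lower mitotic and pan-neuronal lists go in the same direction as the number of genes above 0, which was 15882 to 16767 in Kdm4a shRNA and 16803 to 18609 in control libraries.

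A candidate explanation for the lower mitotic genes is that proliferating cells were fewer among the sorted cells with Kdm4a shRNA. The camera p of the list, 4.761e-07 with a preset and 0.0142 with an estimated correlation, only restates the pattern and cannot separate fewer cells from lower transcript levels per cell. One library did not set the result, as the largest camera p without any 1 library was 0.00038 with a preset correlation. Trends with GC content and gene length did not account for it, with a limma camera p of 1.335e-07 after their removal. The list median lay at percentile 0 of 10000 random lists matched on mean expression, whose central 95% ran from −0.42 to 0.15. It was thus lower than typical genes of its level. This cannot decide on a loss of low-level genes, since lower cell cycle genes in these same libraries prompted the list. The random lists were also matched on mean expression only, not on how far members vary together. Fewer cells and lower levels per cell both remain open, as do a loss of low-level genes and a difference between the sorted samples that is unrelated to Kdm4a.

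By the medians of their lists, microglial, astrocyte and oligodendrocyte transcripts stood above neuronal ones, although the cells were sorted for EYFP and the design speaks of neurons. The microglial median exceeded the pan-neuronal one in 6 of 6 libraries, by 68.0 to 356 times, which may reflect cells or RNA of other types in the sorted samples. Ctss and C1qb, abundant in microglia, averaged 4121 and 3871 FPKM in control and 5877 and 3135 FPKM in Kdm4a shRNA libraries. Normalization to gene length by the submitters was argued against, since rebuilt fragments differed by at least 26.67 times in every library. The excess of microglial over neuronal markers is the pattern itself, so it leaves the source open: whether EYFP was present in glia or the sort let other cells through was not tested.

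The higher interferon list depended on single libraries, since its largest adjusted p without 1 library was 0.2385, without control library 1. Its median was 0.80 with all libraries, 0.28 without that one and 0.30 without Kdm4a shRNA library 2. Microglial markers did not rise as a list, with 7 positive and 9 negative members and a median log2 fold change of −0.145. Their medians overlapped between the groups, at 210 to 337 FPKM in control and 225 to 398 FPKM in Kdm4a shRNA libraries. A higher share of microglia in the Kdm4a shRNA samples thus found no support but stays open. The interferon median exceeded the microglial one by 0.9428 on the log2 scale, from 0.56 to 1.06 without each library in turn. However, the difference per library overlapped between the groups (two-sided exact permutation test over 3 against 3 libraries, p = 0.2). The expression level of the members was argued against, with the list at percentile 100 of 10000 matched random lists. Also open are a low control library 1, which may set much of the difference, and an effect of the Kdm4a shRNA or its delivery, which was not tested.

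A hypothesis that microglia were more activated with Kdm4a shRNA found no support but stays open. The activation list had a median log2 fold change of −0.45 (limma camera adjusted p = 0.03195 over 3 lists, lower, and adjusted p = 0.38 with an estimated correlation). The median was −0.77 without control library 1 (limma camera adjusted p = 0.0021), −0.34 without control library 2 (adjusted p = 0.29) and −0.30 without control library 3 (adjusted p = 0.016). It was −0.56, −0.25 and −0.60 without Kdm4a shRNA libraries 1, 2 and 3 (limma camera adjusted p = 0.26, 0.11 and 0.0046). The zinc finger list median of −0.41 lay below the central 95% of matched random lists, from −0.25 to −0.01.

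The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 higher and 0 lower genes at an adjusted p under 0.05, which any split reaches, so the comparison says nothing, and the highest other split gave 1 gene. The real split gave 4 lists, and 4 splits, the real one included, gave at least as many, with 6 lists in the highest other split. At an unadjusted p under 0.05 the real split gave 1084 genes, the split that sets control library 1 with Kdm4a shRNA libraries 2 and 3 gave 1480, and that with Kdm4a shRNA libraries 1 and 2 gave 1150.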
